A study of Drosophila melanogaster with 2 samples.

How the data were processed

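Chromosome contacts were measured by Hi-C, which joins and sequences pairs of DNA fragments that lie close together in the nucleus, in Drosophila melanogaster embryos collected 16 to 18 hr after egg laying. The series holds 2 samples of 1 group, ph505, a null allele of polyhomeotic, an X-linked gene for a subunit of Polycomb repressive complex 1. Per the labels' protocols, the stock carried the mutant X over an FM7c balancer with a GFP reporter, and embryos without GFP, the hemizygous mutant males, were picked on a large-particle sorter from collections of about 3000 embryos. The genotype label names the mutant and balancer chromosomes together, so the sort is known only from the protocol. No wild-type map was analysed here, and no difference between genotypes was tested.

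The deposited contact tables hold raw counts of contacts per pair of bins at 6 bin sizes, 5, 10, 20, 40, 80 and 160 kb, with both samples pooled into 1 map. Bowtie and the build dm3 are named in the submitters' processing notes; the version, the restriction enzyme, and the filters on read pairs are not given in the sources used here. Each pair of different bins was listed in both orders and was counted once here. The tables at 5, 10 and 20 kb held pairs of the same arm up to 5, 10 and 20 Mb apart, and those at 40 kb and above held all pairs. Per the file headers, a second column gives the authors' expected count, which in its values was close to a product of 2 bin factors with no dependence on distance. A bin table adds a whole number per bin that was taken, from its values, as the number of usable mapping units.

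The map held 50784077 contacts at 40 kb, of which 29550524 joined bins of the same arm. At 5, 10 and 20 kb, 23053890, 26729820 and 29334094 same-arm contacts were held. Because the samples were pooled, no value has a replicate error. Exact Clopper-Pearson and Poisson intervals, at 95%, cover counting error only, and bootstraps of 1000 draws over blocks of 1 Mb or over domains cover variation along the genome only. Reads without molecular identifiers are not independent molecules, so counting intervals are too narrow.

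Bins with under 25% of their arm's median contacts were masked. Same-arm maps were balanced by iterative correction, with the main diagonal and its nearest neighbour on each side skipped. The decay exponent was the least-squares slope of log10 mean balanced contact on log10 distance in 10 kb bins, from 50 to 500 kb and from 500 kb to 5 Mb. Borders were minima of the insulation score in 10 kb bins with a window of 100 kb and a log2 prominence of at least 0.2. On each side of a minimum, the highest score was taken before the next lower score or the end of the scored stretch. Prominence was the rise to the lower of these 2, which can lie outside the flanking domains. A domain ran from one border bin to the next. Its coordinates include both border bins, and its length is the distance between them. The ratio of contacts within domains to contacts across 1 border was taken at equal distances of 20 to 100 kb. Compartments came from the first eigenvector of the correlation of observed over expected contacts in 80 kb bins, and strength was the mean of the top 20% of bins with itself and the bottom 20% with itself over top with bottom. The eigenvector's sign was set so that the top side had the higher share of contacts with other arms, since gene density was not used here. Contacts between whole arms were set against the product of the arms' totals at 160 kb. Those between arm ends of 2 Mb were set against the product of the bins' contacts with the other arm of that pair. For chromosome 4, the expected count of an end came from its share of its arm's contacts with the other large arms.

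Long-range contacts were pairs of 20 kb bins on one arm at least 500 kb apart that expected at least 5 contacts from distance and bin coverage, exceeded the expected count at least 2-fold, and passed a one-sided Poisson test with Benjamini-Hochberg adjustment at 0.05. Touching pairs were merged into clusters. The Poisson model has no term for spread beyond counting, so a call says only that the pooled count exceeded the distance model. Calculations used Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3, with plots by matplotlib 3.10.9.

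The steps were tested on simulated maps drawn from the real decay and coverage. A map without domains gave 130 borders and a within-to-across ratio of 1.00. Borders planted with contacts lowered 1.5-fold and 2-fold were found within 20 kb in 88.2% and 94.0% of cases. A map without long-range contacts gave 0 clusters, and planted contacts of 2-, 3- and 5-fold were found in 8%, 93% and 100% of cases, with 0, 19 and 39 called pairs elsewhere. A planted slope of -1 came back as -1.00. A planted compartment strength of 1.56 came back between 1.45 and 1.49 over the 5 large arms, and a map without compartments gave 0.947 to 0.966.

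The main tests, their first alternatives and the rule for the regions named were fixed before the data were examined. Further tests and alternatives were added after the data had been seen. The rule names the 10 strongest long-range clusters, the 5 longest domains and the 5 domains with the strongest borders, taken as the highest mean prominence of the flanking borders. It also named genes by symbol, but the annotation at hand is of Release 6 of the genome, another build than dm3, so its coordinates were not used and regions are named by their bins. For the same reason the planned coverage of the ph locus, the contacts among lists of Polycomb target, housekeeping and tissue-restricted genes, the share of listed genes at borders and the lengths of domains with Polycomb targets were not analysed here. The alternatives tried were other bin sizes, masks, windows, prominences, fold limits and end lengths, raw counts, and the authors' expected counts in place of balancing.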

Results

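A pooled Hi-C map of embryos sorted for ph505, labelled a null allele of the Polycomb gene polyhomeotic, was described from its 50784077 contacts. The 2 samples of the group were merged in the map, so there was no replicate error and no second genotype to compare. Of all contacts, 58.2% (exact Clopper-Pearson 95% interval 58.17 to 58.20) joined bins of the same arm and 21233553 joined different arms. Coordinates are those of dm3.

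The first question was whether the map had the X coverage of males, as the protocol describes a sort for hemizygous mutant males. The median 40 kb bin of X had 19194 contacts, against 34660 over the autosomal arms 2L, 2R, 3L and 3R. The ratio was 0.554 (block bootstrap 95% interval 0.503 to 0.604), near the 0.5 of a single copy. The medians of single arms were 32635 contacts on 2L, 36285.5 on 2R, 33961 on 3L and 35822 on 3R, and chromosome 4 had 30020. Counting contacts with other arms alone, the X to autosome ratio was 0.650 (0.584 to 0.715). For contacts per bin 0.5 is not an exact expectation. Autosomal bins have the single X among their other arms, whereas X bins have autosomes only. An excess over 0.5 in these 2 ratios is therefore no measure of extra X copies. Per authors' expected count, contacts within X relative to those within autosomal arms rose with distance. The ratio was 0.444 (0.412 to 0.484) at 40 to 200 kb, 0.528 (0.505 to 0.553) at 1 to 2.44 Mb and 0.614 (0.588 to 0.642) at 5 to 9.96 Mb. X with autosomes stood at 0.599 (0.588 to 0.609) of arms of different autosomes. These ratios by distance were chosen after the coverage ratio had been seen.

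The next comparison was of how contacts fell with distance on each arm. Contact frequency fell most slowly on X. Between 50 and 500 kb the exponent was -1.09 on X, against -1.15 on 2L, -1.14 on 2R, -1.19 on 3L and -1.18 on 3R (mean of the 4 autosomal arms -1.16 ± 0.024, SD over arms). Between 500 kb and 5 Mb it was -0.47 on X, against -0.57 on 2L and -0.53 on each of 2R, 3L and 3R (mean -0.54 ± 0.018). X lay outside the autosomal range at both scales, but arms are parts of 1 map, and a permutation of 1 arm against 4 cannot give a p below 0.2.

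**Figure D1:**
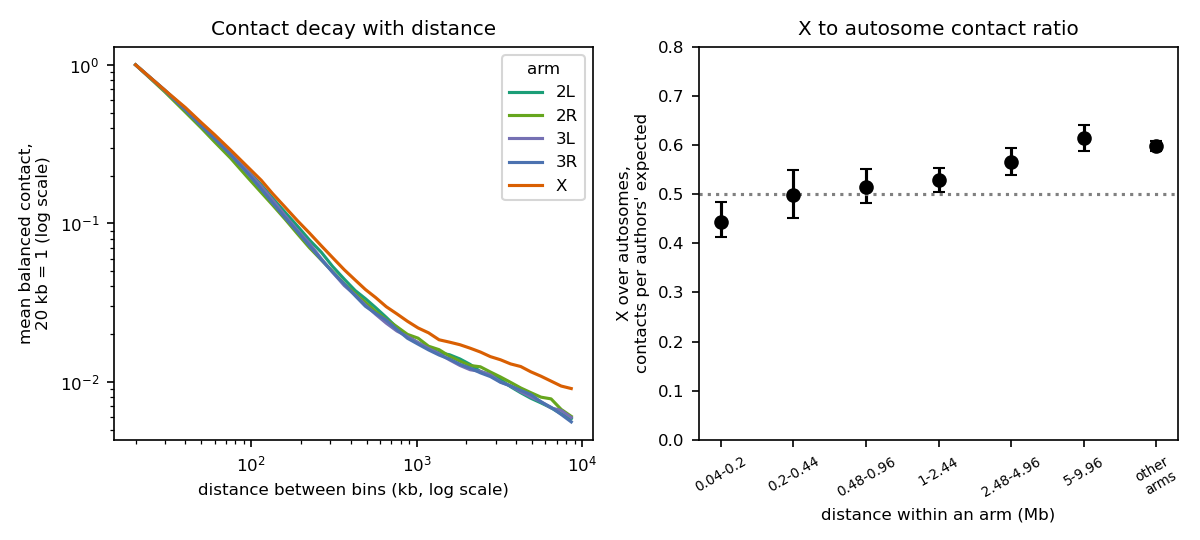
Left, mean balanced contact by distance for the 5 large arms on log axes, scaled to 1 at 20 kb; the X curve runs above the 4 autosomal curves from about 100 kb on. Right, the X to autosome ratio of contacts per authors' expected count by distance within an arm in Mb and, last, for contacts with other arms (points, ratio; bars, 95% block bootstrap); the ratio runs from 0.444 to 0.614.

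Domains, the subject of the series, were present along all 5 large arms of the mutant map. In total 646 borders set off 631 domains with a median length of 160 kb (quartiles 120 and 210 kb, range 40 to 480 kb). Of the borders, 290 (44.9%) had a prominence of at least 1 on the log2 scale, and 203 domains were at least 200 kb long. Median domain length was 160 kb on 2L, 150 kb on 2R, 170 kb on 3L, 160 kb on 3R and 170 kb on X, with 122, 117, 124, 164 and 119 borders. The longest domains were 2L 17470001 to 17960000 (480 kb), X 8970001 to 9450000 (470 kb), 3L 22250001 to 22720000 (460 kb), X 11920001 to 12360000 (430 kb) and 3L 17040001 to 17470000 (420 kb). The same X domain at 8970001 to 9450000 had the strongest borders by mean prominence, at 2.71. Next came 3L 15150001 to 15500000 (2.71), 2L 9890001 to 10210000 (2.64), 3R 8540001 to 8810000 (2.56) and 3L 12850001 to 13040000 (2.55). Prominence is set against scores that can lie far from a border, so the order is not one of contrast with the flanking domains. Borders of high prominence did not always enclose dense contacts. Observed over expected contacts inside were 0.734 in the X domain, 0.849 in 3L 12850001 and 0.920 in 2L 9890001, but 1.28 in 3L 15150001 and 1.37 in 3R 8540001. In the X domain the insulation score was above the arm's mean only in bins starting at 9290001 to 9380001. The rest was a stretch of low scores in which no dip reached the prominence limit of 0.2, so its length depends on that limit. The long 2L domain at 17470001 had weak borders, with a mean prominence of 0.581, and lost 1 of its borders with a window of 200 kb or with raw counts. The 3L domain at 12850001 lost 1 border with a window of 200 kb, with raw counts and with the authors' expected counts. A map simulated without domains gave 130 borders, with a median prominence of 0.25 and a highest of 1.00, against a median of 0.87 here. With the contacts split once at random into 2 sets, 606 of 662 borders of one set (91.5%) lay within 20 kb of a border of the other. The split is of the pooled counts, so this share covers counting error and not a difference between the 2 samples. The share that random positions would give was not computed.

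Contacts within domains exceeded those across borders. At equal distances of 20 to 100 kb, bin pairs inside a domain had 2.27 times the contacts of pairs across 1 border (bootstrap over domains, 2.20 to 2.34). The arms lay close together, at 2.30 on 2L, 2.25 on 2R, 2.22 on 3L, 2.26 on 3R and 2.35 on X, with overlapping intervals. Against the distance model, the median domain held 1.18 times the expected contacts, and 465 of 631 domains (73.7%) were above 1. Since borders were called on the same contacts, the ratio was also taken with the contacts split at random into 2 sets, borders from one and counts from the other, an alternative added after seeing the data; it gave 2.23.

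**Figure D2:**
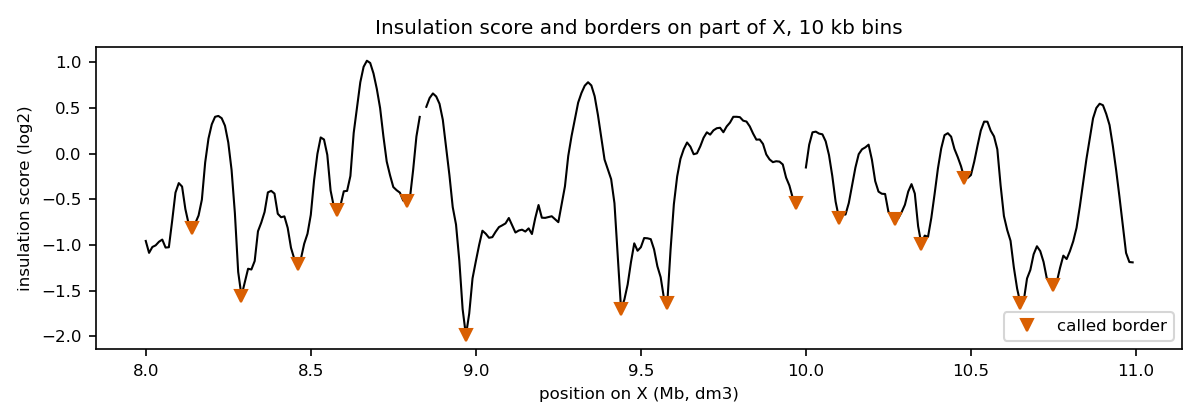
Insulation score (log2) in 10 kb bins along X from 8 to 11 Mb, with the 15 called borders as triangles. The deep minima at both sides of the domain from 8970001 to 9450000 have the highest mean prominence of the map, 2.71. Between them the score is above the arm's mean only in bins starting at 9290001 to 9380001.

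Each large arm separated into groups of bins with like contacts. Compartment strength in 80 kb bins was 1.67 on 2L, 1.39 on 2R, 1.51 on 3L and 1.53 on 3R (mean 1.53 ± 0.117, SD over arms), and 1.92 on X. X was above each autosomal arm, also with the autosomes thinned at random to the depth of X, which gave a mean of 1.54 and was added after seeing the data. Bins on the top side had a median of 47.5% of their contacts with other arms on 2L, against 37.8% on the bottom side. On 3L the medians were 46.8% and 38.2%, on 3R 43.4% and 34.1%, and on X 54.2% and 45.6%. On 2R the gap was smallest, 48.2% against 41.2%, and the correlation of the eigenvector with that share across bins was 0.395, against 0.699 to 0.828 on the other arms; bins are not independent replicates. The side called top was set by that share, so only the size of the gap is measured.

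Arms of the same chromosome contacted each other above the product of their totals. The ratio of observed to expected contacts was 1.08 for 2L with 2R and 1.05 for 3L with 3R, while large arms of different autosomes lay between 0.961 for 2R with 3L and 0.977 for 2R with 3R. Chromosome 4 with the autosomal arms ran from 0.941 for 2R to 1.03 for 3L. Chromosome 4 with X stood at 1.09 (exact Poisson interval 1.08 to 1.09), the highest of its 5 pairs. With the authors' expected counts it was the lowest of them, at 1.03, against 1.56 to 1.67 with the autosomal arms. Those counts leave the lower totals of X in place. On them X with the autosomal arms stood at 0.674 to 0.699, and arms of different autosomes at 1.12 to 1.16. The order of the 5 pairs therefore depends on whether arm totals are removed. With the arm totals removed, X with the autosomal arms lay between 0.995 and 1.00. The fit matches each arm's total, so the pairs of an arm must average about 1, and these values do not measure the level of X contacts. For the same reason, values below 1 for arms of different autosomes follow in part from those above 1 for arms of one chromosome.

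The ends of arms contacted ends of their own kind. Ends near the centromere contacted each other at 1.21 times the expected count (exact Poisson interval 1.20 to 1.22), from 1.08 for 3R with X to 1.73 for 2L with 2R; with the authors' expected counts the value for these ends was 1.62. Ends near the telomere contacted each other at 1.17 times it (1.16 to 1.17), from 1.07 for 2L with X to 1.31 for 2R with 3R. Ends of opposite kinds stood at 0.908 (0.904 to 0.912). All 10 arm pairs were above 1 for both kinds of end. The pooled values include arms of one chromosome, 2L with 2R and 3L with 3R (1.19 near the centromere, 1.24 near the telomere). Between different chromosomes, centromere-near ends ran from 1.08 to 1.21 (2R with 3L) and telomere-near ends from 1.07 to 1.31. The order of the 2 pooled values therefore does not rank contacts between different chromosomes. Chromosome 4 contacted the ends near centromeres at 1.36 times the expected count (1.34 to 1.37) and those near telomeres at 0.889 times (0.881 to 0.897), with X telomere-near bins at 1.02.

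**Figure D3:**
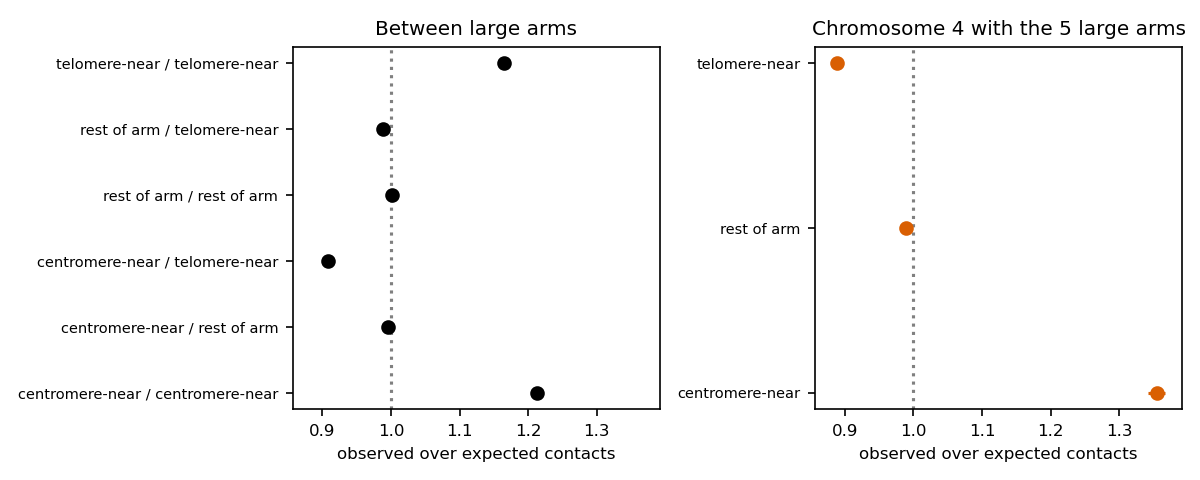
Observed over expected contacts between zones of different large arms (left) and of chromosome 4 with zones of the large arms (right); points are ratios, bars exact Poisson 95% intervals, mostly smaller than the points, and the dotted line marks 1. Like ends lie above 1, at 1.21 and 1.17, and opposite ends below it, at 0.908.

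A search for long-range contacts within arms found a small set of strong, focal pairs over a broad field of weak ones. Of 898563 bin pairs tested, 23691 (2.64%) were called, in 11588 clusters; 8277 clusters were single bin pairs, and 89 reached 5-fold and 15 reached 10-fold. The number of clusters depended on the settings, with 5605 in 40 kb bins, 18158 with distance alone as the expectation, 2412 at 3-fold or more and, added after seeing the data, 1135 of 4 or more touching pairs. The strongest joined 2L 20120001 to 20140000 with 2L 21700001 to 21720000, at 260 contacts against 6.72 expected (38.7-fold, exact Poisson interval 34.1 to 43.7), with 3 masked bins within 200 kb of each anchor. Next was 3L 12840001 to 12860000 with 3L 19980001 to 20000000, 7.14 Mb apart, at 175 against 5.95 (29.4-fold, 25.2 to 34.1). The pair 2L 6360001 with 2L 9460001 had 141 contacts and was 24.2-fold above expected. On 3L, 6640001 with 9320001 had 123 contacts (17.4-fold) and 4800001 with 6980001 had 145 (12.5-fold). On 3R, 19360001 with 24500001 had 94 contacts (17.4-fold) and 19420001 with 24460001 had 62 (11.2-fold). On 2L, 900001 with 2580001 had 111 contacts (13.0-fold) and 19580001 with 20220001 had 125 (12.9-fold). On 3L, 12840001 with 18740001 had 71 (12.4-fold). These 10 clusters are not 10 independent sites, because 2 of those on 3L share the anchor at 12840001 the 2 on 3R lie within 60 kb of each other, and 2L 20120001 and 2L 20220001 are 100 kb apart. In 40 kb bins the 10 ran from 5.36- to 37.4-fold, and 6 were lower by over 1.5 times, among them 3L 12840001 with 19980001 (13.9-fold), 3L 6640001 with 9320001 (7.70-fold) and 2L 19580001 with 20220001 (5.36-fold). With distance alone as the expectation, those that could be tested ran from 8.87- to 31.2-fold, and 3L 4800001 with 6980001 was higher, at 21.2-fold.

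The strong contacts were patches of several bins. Over the 10, the median was 15.2-fold at the top pair, 10.1-fold in the 8 pairs around it, 2.59-fold at about 100 kb and 1.17-fold at 200 to 400 kb. X had 7 clusters of at least 5-fold among 50148 pairs tested, 2L 21 among 180812, 2R 26 among 200971, 3L 26 among 202215 and 3R 9 among 264417. Fewer X pairs reached the expected count of 5, so these numbers do not compare the arms at equal depth.

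**Figure D4:**
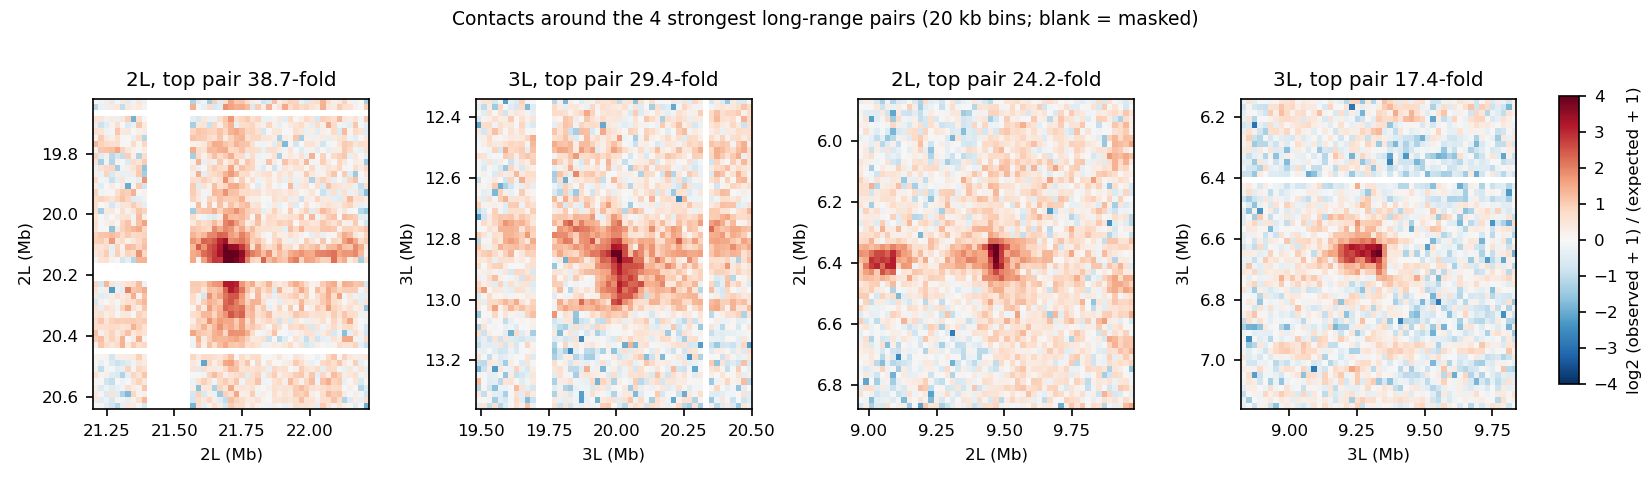
Log2 of observed plus 1 over expected plus 1 contacts in 20 kb bins around the 4 strongest long-range pairs, with positions on the arm in Mb on both axes and masked bins blank. Each map shows a raised patch around the top pair, at 38.7-, 29.4-, 24.2- and 17.4-fold, and the first lies beside masked bins and on a raised column.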

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

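The alternatives with the contacts split at random into 2 sets, per mapping unit, thinned autosomes, larger or more distant clusters, ends left out of the search, and all tests at the approximate windows of the Hox complexes were chosen after the data had been seen. Of 67 alternative values for the main results, 39 stayed within the limits set for a change. This count is not a measure of stability. The same-arm share and the ratios of whole arm pairs sum the same contacts at 40, 80 and 160 kb, so other bin sizes could not change them. The limit for border counts was wide, so that 446 and 949 borders counted as unchanged. X kept the slowest decay and the highest compartment strength under each alternative run for them. Border counts ran from 446 (window 200 kb) to 949 (window 50 kb), and the 18 values of named contacts that could be tested in 40 kb bins or with distance alone were still called. The 2 contacts at 3L 12840001 have no value with distance alone, where they expected 4.22 and 4.43 contacts, under the limit of 5. Named domains kept both borders in 85 of 90 checks. The checks with prominence limits of 0.1 and 0.4 follow from the prominences already measured, since a lower limit keeps every border. No check asked whether added borders split a domain, so the rank of the longest domains was not tested. The contact of the Hox windows turned from 1.17 to 0.85 with distance alone as the expectation. The X to autosome ratio was 0.65 from contacts with other arms, and the same-chromosome share 68.9%. Compartment strength was 1.74 at 40 kb, 1.27 at 160 kb and 1.69 from raw counts. The decay exponents were -1.20 with the authors' expected counts (50 to 500 kb) and -0.51 with raw counts (500 kb to 5 Mb). Contacts of centromere-near ends were 1.20 at both 80 and 40 kb, 1.38 with ends of 1 Mb, 1.10 with 4 Mb and 1.62 with the authors' expected counts. Telomere-near ends gave 1.16 at 80 and 40 kb, 1.30, 1.10 and 1.28. With the authors' expected counts 2L with 2R was 1.28, 3L with 3R 1.22 and 4 with X 1.03. Clusters numbered 2412 at 3-fold, 5605 at 40 kb, 18158 with distance alone and 1135 with 4 or more touching pairs; fewer pass a higher limit by construction. The within-to-across ratio was 2.17 (window 50 kb), 1.96 (raw counts) and 2.71 (authors' expected counts). Except for the cluster limits, the cause was not tested. The other settings foreseen for the ph locus and for the gene lists were not run, for lack of gene positions in dm3, nor was the Hox contact at 10 kb, since that table ends at 10 Mb. No paired analysis was possible because the samples were pooled in 1 group. Depth limits the long-range search to pairs expecting 5 contacts, which few X pairs do, and planted 2-fold contacts were found in 8% of cases.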

Other observations

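All tests in this part were chosen after the values had been seen. Strong long-range contacts shared anchors. The 45 clusters of at least 5-fold and at least 2 Mb apart used 41 anchor regions, with anchors within 200 kb merged, in 27 region pairs. In 10 regions there were 2 or more partners. The region 3L 12740001 to 13020000 had 5 partners, the most of any. It made the single closed triple, with 3L 16100001 to 16120000 and 3L 21500001 to 21540000. Region pairs were 5.17-fold above expected for 12740001 with 16100001, 6.31-fold for 12740001 with 21520001 and 5.59-fold for 16100001 with 21500001.

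Between arms, 97 of 1715317 pairs of 40 kb bins were called. In 84 of them (86.6%) both bins lay within 2 Mb of an arm end, against 2.86% of the pairs tested. Many were neighbours: merged where they touched, they made 46 clusters, 36 of them (78.3%) near ends, and the 3 largest held 40 pairs. Many of the near-end clusters of 1 pair joined the centromere-near ends of 2L and 2R, for example 2L 22880001 to 22920000 with 2R 560001 to 600000 (5.08-fold). These are arms of one chromosome, so the share near ends is not one of contacts between different chromosomes alone. The largest, with 23 pairs, joined 2R 20800001 to 21160000 with 3R 27720001 to 27920000, both near telomeres. The strongest was an exception, 3L 11640001 to 11680000 with 3R 24320001 to 24360000, at 133 contacts against 6.93 expected (19.2-fold, exact Poisson interval 16.1 to 22.8), with 1.99-fold in the pairs around it. The pair 2R 21080001 with X 2160001, which has only its 2R bin within 2 Mb of an end, was 8.30-fold with 0.895-fold around it.

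X contacted the autosomes at 0.599 of the level among autosomes, above the 0.5 of a single copy; embryos with 2 X chromosomes in the sort may contribute, and the excess would need 16.5% of all X chromosomes to be extra ones. Extra copies would raise contacts within X alike, yet the ratio at 40 to 200 kb was 0.444; it rose to 0.614 at 5 to 9.96 Mb, and contacts between paired homologs, counted as one autosomal arm, may lower the short-range value, so that a bound set on it alone was given up and copies stay open. For the FM7c balancer, a multiply inverted X, a scan for inversion junctions gave no stable answer: 4 block sizes were tried, the highest estimate on X ran from 1.99% (100 kb) to 5.97% (200 kb), above maps simulated without inversion at all 4, as were 12 of 16 autosomal estimates, X was the highest arm at 1 of the 4, and it reached the lowest of 10 simulated inversions carried by 8.26% of X chromosomes at 2 of the 4. At all 4 sizes X lay below the lowest estimate simulated for the whole 16.5% (5.26% at 60 kb, 8.53% at 100 kb, 9.31% at 200 kb and 10.1% at 400 kb). The simulated maps held no domains or compartments, and each had 1 inversion with both junctions among unmasked bins. Real estimates need not reach the same level, so this cannot decide whether a balancer carried the whole excess. A biological difference of the X was not tested, since no other genotype was analysed here.

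The focal contacts may be loops or clustered loci, or they may be technical. Misplaced reads of a repeat within a single bin raise the row or column of that bin. Pairs with both bins 20 to 40 kb off the top pair were 5.62-fold above expected (median of the 10). This argues against such a repeat as the whole cause for the set. Of the 10, 9 were at 3-fold or more and 3L 4800001 with 6980001 was at 2.93. A misplaced stretch of several bins would raise these pairs too, so it is not excluded. The strongest contact, on 2L, has 3 masked bins within 200 kb of each anchor and lies on a raised column. A rearranged chromosome in the stock stays open. The excess at 200 to 400 kb in the highest quadrant was 0.78 of what a junction with the arm's own decay would give. This is the median of the 10, which were widely spread, from 0.339 to 2.24. By contrast, the lowest quadrant at 40 to 100 kb, which a junction would leave near 1, had a median of 1.84 over the 10 and ran from 1.03 to 2.69. A first bound, that a junction keeps at least 50% of the top value there, was dropped because it ignored that decay. No biological explanation was tested.

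A contact between the Antennapedia and bithorax complexes, Hox clusters repressed by Polycomb proteins and known to meet in wild-type flies, could be weakened in this mutant. Windows were set on 3R from general knowledge, without an annotation of this build, so their fit to the complexes is unchecked. They fall on the domains from 2480001 to 2910000 and from 12470001 to 12820000 and had 619 contacts against 527 expected (1.17-fold, exact Poisson interval 1.08 to 1.27), the 76.0th percentile of 10000 random window pairs at a like distance (one-sided permutation p = 0.24). In 40 kb bins it was 1.22-fold (86.4th percentile). With the authors' expected counts scaled by distance, in 20 kb bins, it was 1.11-fold (86.4th percentile). With distance alone as the expectation it was 0.85-fold (33.8th percentile). Taken whole, the windows did not stand out from their arm. They run from 2.5 to 2.8 and from 12.5 to 12.8 Mb, and in 20 kb bins the 95th percentile of the random pairs was 1.39. The 10 strongest contacts of this map had fallen to a median of 2.59-fold at about 100 kb. A focal contact inside the windows could therefore be averaged out, and its presence cannot be decided here. Without a wild-type map, a weakened contact cannot be told apart from one that was never strong at these windows.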
